A study of Homo sapiens with 60 samples.

How the data were processed

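RNA of 14 APEX2 constructs in Flp-In HEK293 cells was counted per gene in streptavidin pulldowns and in the RNA before pulldown. Per the labels, cells were given 500 µM biotin-phenol for 30 minutes and 1 mM hydrogen peroxide for 1 minute. The values are raw read counts per gene as deposited, whole numbers with no normalisation, and the authors' processing notes name STAR 2.7.4a, featureCounts and the genome build hg38 for them; the version of featureCounts, the annotation and the strand of counting are not given in the sources used here. Replicates were deposited as separate columns of counts. Each of the 2 tables had 60591 gene rows; 1 was left out for a cell that is no number, and 60590 were used. Of these, 37352 were matched to the reference annotation (GRCh38) by symbol and 705 by synonym, and 22533 were not matched and have no biotype or position. The annotation gives gene spans only, so exons and introns were not used and intron retention was not analysed here. Without strand, antisense and overlapping genes share counts, and reads of paralogs cannot be assigned.

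Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group, which left 23681 genes in the table of 56 libraries and 18641 in the second table. Library sizes were scaled by TMM, and a quasi-likelihood model (glmQLFit, robust) with 1 mean per bait and fraction was fitted to all 56 libraries, with 28 residual degrees of freedom and 9.34 prior degrees of freedom. The second table was fitted alone, with 2 residual degrees of freedom. Enrichment was pulldown minus input on the log2 scale, and each bait's enrichment was compared with that of NLS (for speckles the mean of SRSF1, SRSF7 and RNPS1, for PML bodies the mean of PML and SP100). All 14 comparisons used glmQLFTest, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Log2 CPM used a prior count of 2. The labels do not state that replicates were separate cultures, so the p-values measure the spread between these libraries. Confidence intervals for shares of counts were not used; such intervals cover counting error only. The 2 GFP inputs were closer than other replicate pairs (chi-square per degree of freedom 1.31, p = 9.67e-147) and were kept as 2 libraries.

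Gene groups were 34 lists, fixed with 850 named members, by class of RNA, chromosome, pathway, body and cell type; 0 members were absent from the tables, and 31 lists had the 5 tested members needed in a comparison. The list of coding genes with 1 exon was not used because the annotation has no exon numbers. Lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 431 pairs of list and comparison; beside it camera was run with an estimated correlation, and fry, whose p-value tests whether the genes of a list move on balance in the same direction, and whose mixed p-value tests for change in either direction, neither compared with other genes. Medians are over all tested members of a list. Genes were named by rule: the 10 highest and 10 lowest log2 differences for the speckle, LMNA and FBL baits against NLS, for speckle against LMNA and for poly(A) selection, and the 4 highest and 4 lowest elsewhere, among coding and long noncoding genes past the threshold with a mean CPM of 5 or more and the same direction in both replicates of each bait; the bait genes and landmark noncoding RNAs; and up to 4 members with the smallest adjusted p of each list described. A gene that more than 1 part of the rule named counted under each. Some genes that the rule named are not reported here. The comparisons, lists, naming rule and most alternatives were set before the data were examined.

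The steps were tested on counts simulated from a negative binomial distribution with the mean level and spread of each gene and the library sizes seen here, in which 200 genes were changed per bait or body. Of genes changed 1.5-, 2- and 4-fold, the share recovered was 15.6%, 42.6% and 68.8% for the GFP pulldown, 12.1%, 27.3% and 71.7% for the FLAG pulldown, 0%, 38.5% and 69.8% for speckle, 4.8%, 30.6% and 65.6% for PML body, 1.6%, 6.1% and 44.6% for SAM68, 1.6%, 4.8% and 55.7% for SMN2, 3.1%, 9.7% and 50% for WRAP53, 1.7%, 16.7% and 53.2% for NPAT, 0%, 19.7% and 56.9% for FBL, 3.4%, 21.3% and 61.3% for LMNA, 5.9%, 39.7% and 72.8% for speckle against LMNA and 56.9%, 78.1% and 93.7% for poly(A). Between 2 and 9 of the unchanged genes of a comparison were called where any gene was changed, 0 for the NLS pulldown, where none was, and 2 for NLS against GFP and FLAG among the genes changed in neither. In limma camera a list of 67 raised genes was called higher, and 0 of 50 lists of unchanged genes were called at a p under 0.05.

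Alternatives were DESeq2 1.42.0 (Wald test), DESeq2 size factors in edgeR, total counts, TMM without mitochondrial and small RNA genes, no filter beyond 1 count, a mean CPM of 5 or more, bait and replicate number as a block, a fit on the libraries of the contrast alone, the mean of NLS, GFP and FLAG as reference, pulldowns without inputs, and leaving out each library in turn. Comparisons within 1 library set and without both odd inputs were chosen after seeing the data. Library sets were drawn from the counts of pseudogenes RPS14P8 (above 100 in set I) and RPS3AP21 (at most 1 in set III); the labels name no library batch. Gene length is the span of the gene in GRCh38, long above 100 kb and short below 10 kb, over 11742 of the 12265 genes with a mean CPM of 5 or more (95.7%). Correlations with length are across genes, which are not independent replicates. Tables were read and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.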

Results

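Gene counts were measured for RNA collected by APEX2 proximity labelling in Flp-In HEK293 cells, a human embryonic kidney line. In this assay a protein of interest is fused to the engineered peroxidase APEX2, a short pulse of hydrogen peroxide turns biotin-phenol into a reactive radical, and RNA within reach of the bait is biotinylated and captured on streptavidin. 14 FLAG-tagged APEX2 constructs were profiled: SRSF7, SRSF1 and RNPS1 of nuclear speckles, the RNA-binding protein SAM68 (gene KHDRBS1), PML and SP100 of PML bodies, SMN2 and WRAP53 of gems and Cajal bodies, NPAT of histone locus bodies, FBL (fibrillarin) of the nucleolus, LMNA (lamin A) of the nuclear lamina, and as references a nuclear localisation signal (NLS), GFP and FLAG alone. Each construct had 2 pulldown libraries and 2 libraries of the RNA before pulldown (input), 56 libraries in 28 groups. A second table held 2 poly(A) and 2 ribosome-depleted libraries of SRSF7 pulldown RNA. Total counts were between 14038645 and 56256915 in the inputs, between 19280434 and 42097988 in the pulldowns and between 23522546 and 30511742 in the second table. Mitochondrially encoded genes took between 0.378% and 2.569% of input counts and between 0.2% and 1.101% of pulldown counts. Differences are log2 values ± standard error, with n = 2 libraries per group.

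The pseudogenes RPS14P8 and RPS3AP21 split the libraries into 3 sets that the groups did not explain. Set I held the 16 inputs of FBL, GFP, NPAT, RNPS1, SAM68, SMN2, SP100 and WRAP53, with RPS14P8 between 395 and 1078 counts. Set II held the other 12 inputs and the 24 pulldowns of 12 baits, with RPS14P8 between 1 and 15 and RPS3AP21 between 9 and 88. Set III held the LMNA and GFP pulldowns and the second table, with RPS14P8 between 19 and 32 and RPS3AP21 between 0 and 1. SRSF7, SRSF1, PML, NLS and FLAG had all their libraries in set II. Values within 1 set are given beside the pooled ones. For LMNA and for the baits with inputs in set I, the within-set values came from pulldowns alone, which also carry differences in RNA level between the lines. Input replicate 1 of FBL and of NPAT had 2191 and 958 of 12109 genes more than 2-fold away from the median of the inputs, and the SRSF1 inputs had 846 and 620.

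Each bait's own gene was higher in its inputs than in the other inputs for 10 of the 11 baits named after a gene. The fold was 7530 for SP100, 31 for WRAP53, 8.49 for LMNA, 8.29 for PML, 3.53 for KHDRBS1, 2.94 for SMN2, 2.4 for NPAT, 2.35 for SRSF7, 2.23 for FBL and 1.9 for RNPS1. SMN1 and SMN2 are near-identical paralogs with uncertain counts, and both SMN2 inputs lay below the highest other input (28.7 CPM). SRSF1 was the exception: its gene had a mean of 0.579 CPM (counts scaled to library size) in its own inputs and a median of 0.842 CPM in the others, too few to measure. Of 28 replicate profiles of pulldown over input, 13 correlated best with the bait's other replicate, 20 at a mean CPM of 5 or more. The count was 23 with the mean of both inputs, which ties replicates by construction.

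The comparison of the NLS pulldown with its input asked what a construct without a domain of its own captured. Histone mRNAs, spliceosomal small nuclear RNAs and mitochondrial transcripts were depleted, and some long noncoding RNAs were enriched: 5792 of the 23681 genes tested passed the threshold, 2207 higher and 3585 lower. Among the replication-dependent histone genes, whose mRNAs end in a stem-loop instead of a poly(A) tail, 38 of 51 fell and 0 rose (40 and 0 adjusted over the list alone). Their median was -2.02 (camera adjusted p = 1.85e-28, adjusted p = 0.215 with an estimated correlation). H4C3 (-2.73 ± 0.18), H4C5 (-2.89 ± 0.21) and H2AC6 (-2.66 ± 0.22) were among them, though counts of histone paralogs are uncertain. Of the spliceosomal small nuclear RNA genes, 15 of 23 fell and 0 rose (16 and 0 adjusted over the list alone). Their median was -1.34 (camera adjusted p = 4.93e-08, adjusted p = 0.074 with an estimated correlation). For the mitochondrially encoded genes, 15 of 24 fell and 1 rose (15 and 3 adjusted over the list alone). Their median was -1.83 (camera adjusted p = 5.16e-10, adjusted p = 0.368 with an estimated correlation). MT-ATP8 (-5.24 ± 0.24) and MT-ND3 (-3.67 ± 0.30) were in this group. Immediate early genes, switched on within minutes of a stimulus, also fell: 24 of 37 fell and 0 rose (24 and 0 adjusted over the list alone). Their median was -0.68 (camera adjusted p = 3.22e-10, adjusted p = 0.442 with an estimated correlation). JUND (-2.15 ± 0.21) and EGR1 (-2.05 ± 0.22) were examples. ZNF503 (-3.75 ± 0.31), PRR36 (-3.62 ± 0.26), CTXN1 (-2.83 ± 0.33) and H4C5 were the genes that fell furthest, with adjusted p from 7.65e-13 to 2.75e-08. Of 2139 long noncoding RNA genes, 296 rose and 63 fell (232 and 51 adjusted over the list alone; camera adjusted p = 3.86e-05, adjusted p = 0.442 with an estimated correlation). LINC01198 (1.66 ± 0.51), MMADHC-DT (1.25 ± 0.25) and MIR31HG (1.20 ± 0.23) and the cytokine gene IL15 (1.19 ± 0.24) rose furthest. RMRP, the RNA of RNase MRP, fell by 2.29 ± 0.30, while NEAT1, the RNA of paraspeckles, rose (0.73 ± 0.26; adjusted p = 0.0352). Leaving out 1 library gave counts of 2840 (NLS pulldown 1), 3372 (NLS input 1) or 3334 (NLS input 2). Scaling by total counts raised the median of all genes by 0.20, and the share that was higher from 38.1% to 67.9%.

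In the GFP pulldown, which asked what a construct outside the nuclear bodies captured, long genes were enriched and short coding mRNAs were depleted: 12763 of the 23681 genes tested passed the threshold, 6430 higher and 6333 lower. Among the cytosolic ribosomal protein mRNAs, 72 of 74 fell and 0 rose (72 and 0 adjusted over the list alone). Their median was -1.62 (camera adjusted p = 6.93e-27, adjusted p = 0.442 with an estimated correlation). RPS27 (-4.18 ± 0.43) and RPS26 (-3.47 ± 0.20) fell furthest. Of the immediate early genes, 36 of 37 fell and 0 rose (36 and 0 adjusted over the list alone). Their median was -1.36 (camera adjusted p = 6.75e-15, adjusted p = 0.368 with an estimated correlation). ZFP36 (-2.45 ± 0.20) and MYC (-1.80 ± 0.15) were examples. For the histone genes, 40 of 51 fell and 1 rose (40 and 1 adjusted over the list alone). Their median was -1.94 (camera adjusted p = 4.62e-13, adjusted p = 0.442 with an estimated correlation). H2BC21 (-3.42 ± 0.43) and the differentiation factor gene PPDPF (-3.39 ± 0.19) fell nearly as far as RPS26. LINC01505 (2.58 ± 0.32), CFAP299 (2.47 ± 0.28) and SOX2-OT (2.37 ± 0.30) rose furthest with NECTIN3-AS1 (2.48 ± 0.35), an antisense transcript whose count is uncertain. Genes longer than 100 kb had a median of 0.74 (1962 of 2572 higher) and genes shorter than 10 kb one of -1.19 (1739 of 2046 lower). The GFP inputs were in set I and the pulldowns in set III, so library set and fraction cannot be told apart here. The median of all genes moved by 0.10 with DESeq2 size factors and by 0.12 with total counts.

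The FLAG pulldown, of the tag alone, was depleted of histone mRNAs and of part of the mitochondrial transcripts and of the genes on chromosome 19: 2940 of the 23681 genes tested passed the threshold, 546 higher and 2394 lower. For the histone genes, 31 of 51 fell and 0 rose (39 and 0 adjusted over the list alone). Their median was -1.19 (camera adjusted p = 7.31e-23, adjusted p = 0.331 with an estimated correlation). H4C3 (-1.72 ± 0.17) and H2AC6 (-2.00 ± 0.21) were examples. For the mitochondrially encoded genes, 12 of 24 fell and 5 rose (14 and 6 adjusted over the list alone). Their median was -1.19 (camera adjusted p = 4.16e-06, adjusted p = 0.442 with an estimated correlation). Of the 1145 genes on chromosome 19, a gene-dense chromosome, 398 fell and 13 rose (491 and 27 adjusted over the list alone; camera adjusted p = 3.3e-15, adjusted p = 0.442 with an estimated correlation). The calcium pump gene ATP2B4 (1.73 ± 0.15) rose furthest, with LINC01237 (0.99 ± 0.20), MINAR1 (0.98 ± 0.19) and the antisense transcript SRP14-AS1 (1.17 ± 0.16). ZNF503 (-2.53 ± 0.27), LINC01578 (-2.48 ± 0.48), PRR36 (-2.42 ± 0.26) and TMEM160 (-2.22 ± 0.41) fell furthest. Without 1 library, the count became 769 (FLAG pulldown 1), 1543 (FLAG pulldown 2), 1380 (FLAG input 1) or 1434 (FLAG input 2). The share that was higher went from 18.6% to 33% with size factors and to 37.2% with total counts, and was 30% without the odd inputs of FBL and NPAT.

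NLS was set against the mean of GFP and FLAG to ask what the nuclear reference added to the other references. Ribosomal protein mRNAs had a higher median with NLS: 1277 of the 23681 genes tested passed the threshold, 763 higher and 514 lower. Among the cytosolic ribosomal protein mRNAs, 34 of 74 rose and 0 fell (63 and 0 adjusted over the list alone). Their median was 0.75 (camera adjusted p = 6.09e-33, adjusted p = 0.442 with an estimated correlation). RPS27 (1.65 ± 0.46), RPS26 (1.49 ± 0.23) and RPL41 (1.41 ± 0.31) and the dehydrogenase gene DHRS2 (1.42 ± 0.28) rose furthest. Of the small nucleolar RNA host genes, 3 of 22 rose and 0 fell (10 and 0 adjusted over the list alone). Their median was 0.46 (camera adjusted p = 7.7e-07, adjusted p = 0.197 with an estimated correlation). SNHG15 was 0.88 ± 0.14. ZNF503 (-1.38 ± 0.40), LHFPL3 (-1.16 ± 0.35) and ZNF609 (-1.02 ± 0.18) and the antisense transcript NECTIN3-AS1 (-1.11 ± 0.34) fell furthest. NORAD, a cytoplasmic RNA that binds PUMILIO proteins, fell by 0.98 ± 0.15. Within set II, NLS against FLAG alone had 729 genes past the threshold, 205 higher and 524 lower. Of these, 386 were also called in the pooled comparison in the same direction. Genes shorter than 10 kb had a median of 0.34 pooled and -0.03 within the set. There the ribosomal protein mRNAs had a median of 0.15 (camera adjusted p = 0.0631), and histone genes a lower one (4 fell and 0 rose, median -0.69, camera adjusted p = 4.96e-10, adjusted p = 0.564 with an estimated correlation). With 1 library left out, the count was 427 (NLS pulldown 1), 283 (NLS pulldown 2), 268 (NLS input 1), 399 (NLS input 2), 762 (GFP input 1), 812 (GFP input 2), 850 (FLAG pulldown 2) or 785 (FLAG input 1). The share that was higher went from 59.7% to 37.1% with size factors and to 80.5% with total counts.

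**Figure D1:**
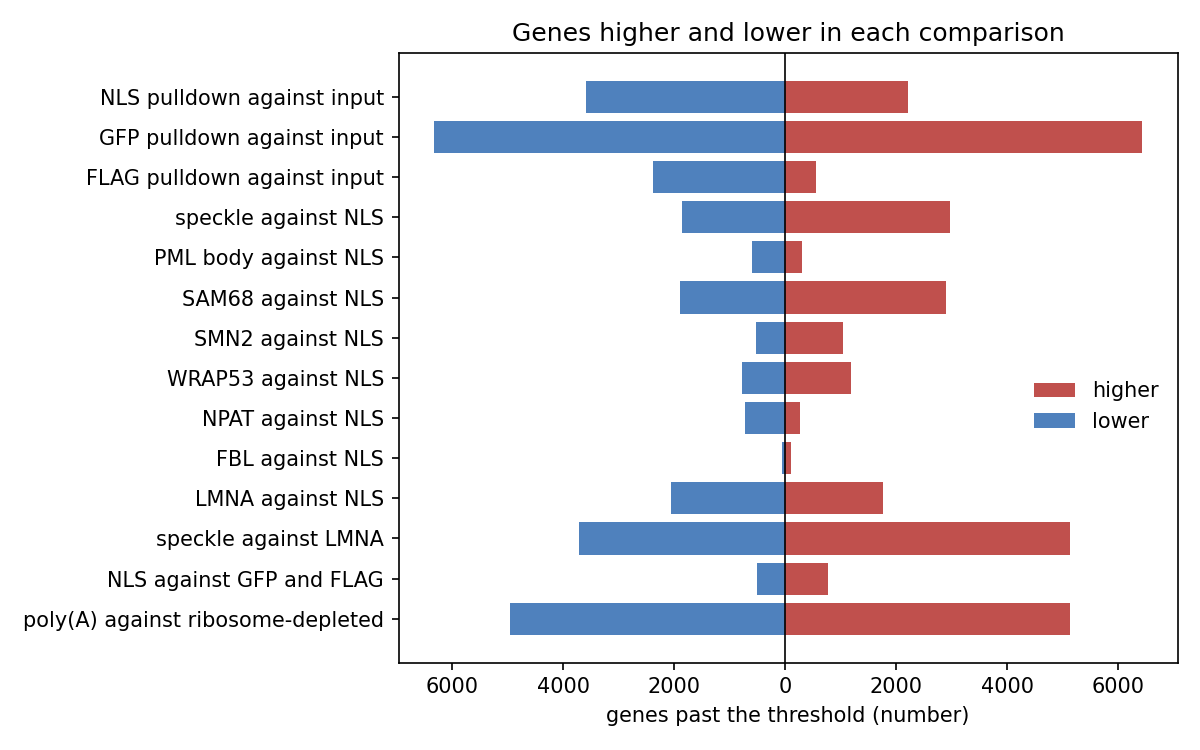
Genes past the threshold in each of the 14 comparisons (number of genes, higher to the right and lower to the left). Counts were highest for the GFP pulldown (6430 higher, 6333 lower) and lowest for FBL against NLS (104 higher, 59 lower).

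Nuclear speckles store splicing factors, and the mean of SRSF1, SRSF7 and RNPS1 was set against NLS to ask which RNAs lie near them. MALAT1, splicing regulator mRNAs and genes known to keep introns were enriched, and the mRNAs of ribosomes, the secretory pathway and the respiratory chain were depleted. Of the 23681 genes tested, 4827 passed the threshold, 2962 higher (1163 by 2-fold or more) and 1865 lower (293 by 2-fold or more). The genes that rose furthest were the deadenylase gene PAN2 (2.14 ± 0.14), ANKZF1 (2.11 ± 0.14) and MSTO1 (2.03 ± 0.24), MALAT1 (2.03 ± 0.27), the long noncoding RNA of nuclear speckles, MIR503HG (2.01 ± 0.21) and MST1 (1.98 ± 0.22), the kinase gene CDK10 (1.95 ± 0.22), BRICD5 (1.93 ± 0.28) and IZUMO4 (1.92 ± 0.27) and the telomere maintenance gene CTC1 (1.88 ± 0.13). Their adjusted p ran from 3.77e-13 to 3.45e-06. MSTO1 has a near-identical pseudogene, so its count is uncertain. In GRCh38, PAN2 lies on chromosome 12, 56316936 to 56334000, ANKZF1 on chromosome 2, 219229806 to 219236679 and MALAT1 on chromosome 11, 65497738 to 65506516. Those that fell furthest were the phosphatase-complex gene MOB4 (-1.70 ± 0.40), SMIM30 (-1.59 ± 0.36) and ARL6IP5 (-1.54 ± 0.26), the metallothionein MT2A (-1.54 ± 0.29), the ubiquitin gene UBB (-1.49 ± 0.22), TMSB10 (-1.48 ± 0.26), the spliceosome gene SF3B5 (-1.40 ± 0.24), DPM3 (-1.40 ± 0.29) and HSD17B12 (-1.39 ± 0.38) and OST4 (-1.38 ± 0.32) of the oligosaccharyltransferase. Their adjusted p ran from 5.24e-06 to 0.00686. In the baits of set II alone, PAN2 was 1.87 ± 0.15, ANKZF1 2.21 ± 0.15, MALAT1 2.11 ± 0.29 and MOB4 -2.00 ± 0.43. Pulldown over input of MALAT1 was 3.39 ± 0.25 for SRSF1, 2.45 ± 0.24 for RNPS1 and 1.97 ± 0.24 for SRSF7 against 0.57 ± 0.23 for NLS. NEAT1, the RNA of the neighbouring paraspeckles, did not differ from NLS (0.33 ± 0.30; adjusted p = 0.508), and it was lower with the speckle baits in pulldowns alone (-1.51). TUG1, a chromatin-associated long noncoding RNA, rose (0.93 ± 0.23), KCNQ1OT1 did not pass (0.63 ± 0.25; adjusted p = 0.0756), and RMRP fell by 1.16 ± 0.33.

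By gene group, genes with known detained or retained introns were enriched near speckles: 20 of 27 rose and 0 fell (21 and 0 adjusted over the list alone). Their median was 0.79 (camera adjusted p = 3.75e-13, adjusted p = 0.074 with an estimated correlation). CCNL2 (1.45 ± 0.13), NSUN5P1 (1.38 ± 0.15), CDK11B (1.20 ± 0.14) and FNBP4 (0.95 ± 0.12) led the group. Of the SR proteins, their kinases and splicing regulators, 32 of 53 rose and 0 fell (34 and 2 adjusted over the list alone). Their median was 0.57 (camera adjusted p = 8.49e-12, adjusted p = 0.288 with an estimated correlation). The kinase gene CLK2 (1.61 ± 0.13), ARGLU1 (0.91 ± 0.11) and CLK3 (0.92 ± 0.12) were among them. For the zinc finger ZNF-named genes, a large family of transcription factors, 145 of 450 rose and 1 fell (158 and 1 adjusted over the list alone). Their median was 0.37 (camera adjusted p = 9.34e-09, adjusted p = 0.215 with an estimated correlation). ZNF75A (1.36 ± 0.12) and ZNF226 (1.29 ± 0.12) were examples. Genes on chromosome 19 had a higher median: 338 of 1145 rose and 42 fell (373 and 47 adjusted over the list alone). Their median was 0.42 (camera adjusted p = 8.55e-07, adjusted p = 0.563 with an estimated correlation). So had immediate early genes: 15 of 37 rose and 0 fell (17 and 0 adjusted over the list alone). Their median was 0.41 (camera adjusted p = 0.000115, adjusted p = 0.563 with an estimated correlation). FOSB (1.40 ± 0.21) and NR4A2 (1.08 ± 0.19) were among these. In contrast, among the cytosolic ribosomal protein mRNAs, 54 of 74 fell and 1 rose (64 and 1 adjusted over the list alone). Their median was -0.90 (camera adjusted p = 1.85e-28, adjusted p = 0.442 with an estimated correlation). RPL15 (-1.29 ± 0.23) and RPL24 (-1.29 ± 0.23) were examples. The secretory and membrane protein mRNAs made at the endoplasmic reticulum fell too: 35 of 55 fell and 0 rose (41 and 2 adjusted over the list alone). Their median was -0.68 (camera adjusted p = 3.3e-20, adjusted p = 0.442 with an estimated correlation). DAD1 (-1.33 ± 0.23) and CD63 (-0.97 ± 0.18) were among them. Of the nuclear-encoded respiratory chain mRNAs, 38 of 62 fell and 1 rose (42 and 1 adjusted over the list alone). Their median was -0.68 (camera adjusted p = 7.45e-19, adjusted p = 0.442 with an estimated correlation). NDUFB3 (-1.10 ± 0.16) and NDUFA1 (-1.10 ± 0.16) were examples. For genes on chromosome 18 the median (-0.12) and the test (camera adjusted p = 0.00573; adjusted p = 0.563 with an estimated correlation) pointed down and the mean (0.04) up. With SRSF1 and SRSF7 alone, within set II, 6009 genes passed, 3705 higher and 2304 lower. Of these, 4566 were shared with the pooled comparison in the same direction. There the genes with detained introns had a median of 0.80 (20 rose, 0 fell; adjusted p = 0.165 with an estimated correlation). The splicing regulators had a median of 0.51, the ribosomal protein mRNAs -0.82 and the secretory mRNAs -0.75. Leaving out 1 library gave counts of 3099 (NLS pulldown 1) or 2879 (NLS input 2). A fit on the libraries of the contrast alone turned the balance, with 4193 higher and 4976 lower. The RNPS1 inputs were in set I.

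**Figure D2:**
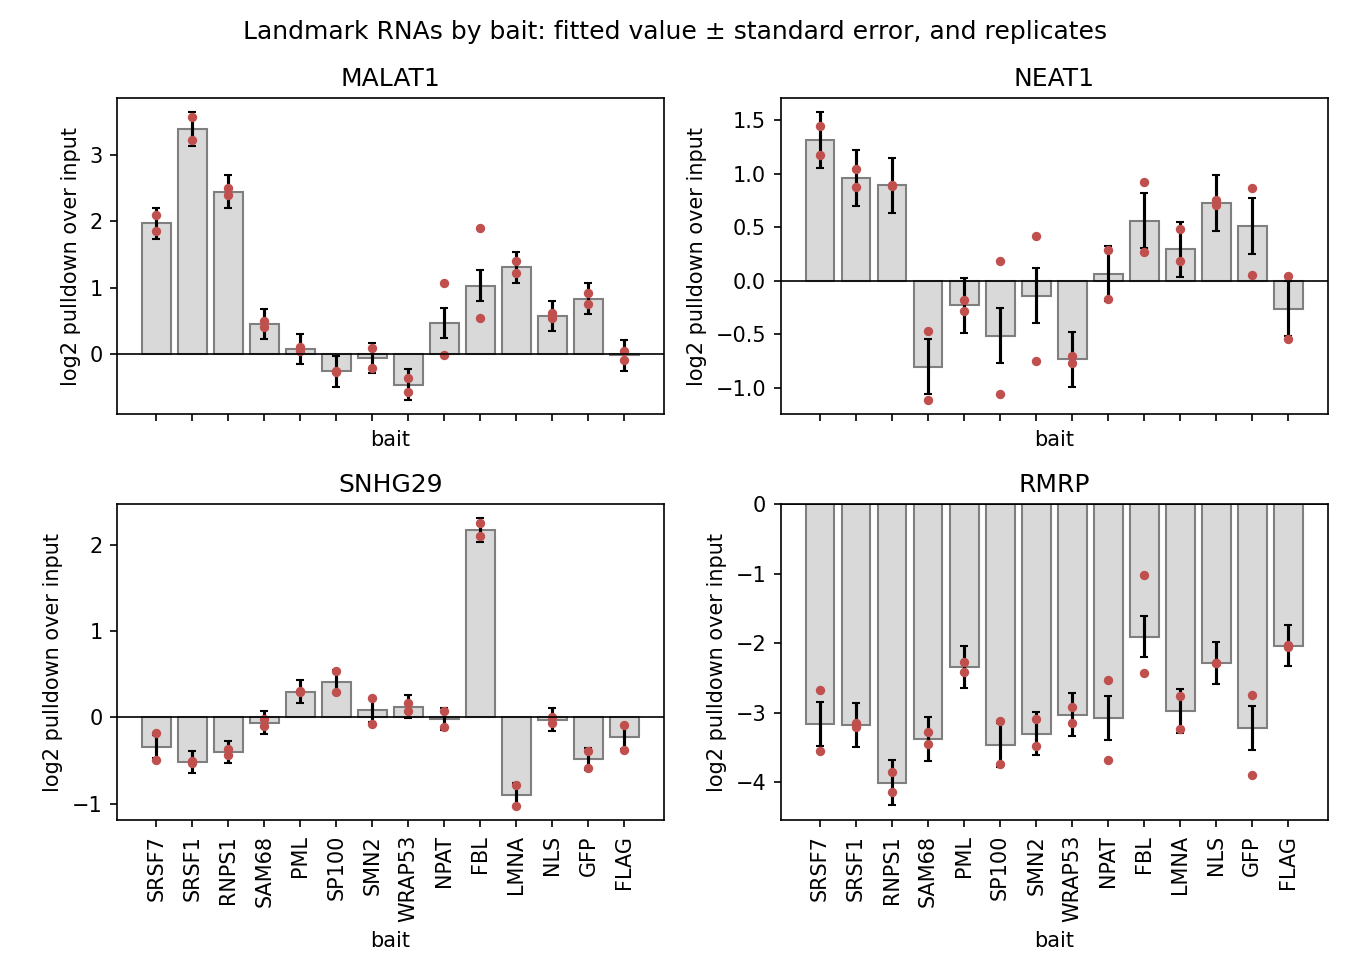
Pulldown over input (log2) of MALAT1, NEAT1, SNHG29 and RMRP for each of the 14 baits, with points for the 2 replicates and bars for the fitted value ± standard error. MALAT1 was highest with SRSF1 (3.39) and SNHG29 with FBL (2.17).

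Speckles lie in the nuclear interior and the lamina at its edge, and the speckle baits were set against LMNA to compare these positions directly. Gene-dense chromosomes, splicing regulators and short genes were on the speckle side, and long genes and chromosome 4 on the LMNA side: 8837 of the 23681 genes tested passed the threshold, 5124 higher and 3713 lower. Higher near speckles were BRICD5 (3.35 ± 0.32), MSTO1 (3.30 ± 0.27), IZUMO4 (3.16 ± 0.32) and PAN2 (2.98 ± 0.15), the fatty acid oxidation gene ACADVL (2.83 ± 0.15), NALT1 (2.82 ± 0.31) and CCDC78 (2.78 ± 0.21), the kinetochore gene CENPT (2.73 ± 0.17), MST1 (2.66 ± 0.23) and PPM1M (2.65 ± 0.22). Higher with LMNA were TMEFF2 (-2.76 ± 0.27), PPFIA2 (-2.42 ± 0.31), CHSY3 (-2.40 ± 0.32), HS3ST5 (-2.37 ± 0.26), GPM6A (-2.36 ± 0.27), GPC5 (-2.32 ± 0.27), GALNT13 (-2.23 ± 0.28), FGF13 (-2.16 ± 0.32), SAMD5 (-2.14 ± 0.26) and ADGRL3 (-2.10 ± 0.25). TMEFF2 lies on chromosome 2, 191949046 to 192194933. Adjusted p for these genes ran from 3.71e-17 to 8.59e-07. Of the SR proteins, their kinases and splicing regulators, 39 of 53 rose and 1 fell (43 and 1 adjusted over the list alone). Their median was 0.73 (camera adjusted p = 1.58e-12, adjusted p = 0.263 with an estimated correlation). Of the genes with known detained or retained introns, 21 of 27 rose and 0 fell (22 and 0 adjusted over the list alone). Their median was 0.98 (camera adjusted p = 1.71e-10, adjusted p = 0.18 with an estimated correlation). NSUN5P1 (2.56 ± 0.17), CCNL2 (1.95 ± 0.13) and CLK2 (2.04 ± 0.13) led these groups. On chromosome 19, 552 of 1145 rose and 18 fell (575 and 20 adjusted over the list alone). Their median was 0.63 (camera adjusted p = 1.58e-12, adjusted p = 0.445 with an estimated correlation). On chromosome 17, 464 of 1005 rose and 30 fell (485 and 35 adjusted over the list alone). Their median was 0.57 (camera adjusted p = 2.61e-10, adjusted p = 0.331 with an estimated correlation). On chromosome 4, 263 of 752 fell and 45 rose (269 and 47 adjusted over the list alone). Their median was -0.57 (camera adjusted p = 1.74e-09, adjusted p = 0.331 with an estimated correlation). MALAT1 (1.30 ± 0.27), NEAT1 (0.76 ± 0.30) and TUG1 (1.11 ± 0.23) were higher with the speckle baits. The LMNA pulldowns were in set III. Within that set, the second-table ribosome-depleted SRSF7 pulldown against the LMNA pulldown, without inputs, had 3417 genes past the threshold, 1934 higher and 1483 lower. Of these, 1473 were shared with the pooled comparison in the same direction. There splicing regulators were higher again (28 rose and 1 fell, median 0.40, camera adjusted p = 2.26e-13, adjusted p = 0.186 with an estimated correlation). So were genes with detained introns (18 rose and 0 fell, median 0.57, camera adjusted p = 3.31e-13, adjusted p = 0.165 with an estimated correlation). PAN2 was 1.17 ± 0.13, BRICD5 1.37 ± 0.27 and TMEFF2 -1.83 ± 0.23. Of the 10 genes higher with LMNA, 7 had the opposite sign there: PPFIA2 (0.92 ± 0.22), CHSY3 (1.65 ± 0.26) and GALNT13 (1.28 ± 0.21) passed that way, and ADGRL3, FGF13, GPM6A and SAMD5 did not pass. GPC5 (-0.50 ± 0.21; adjusted p = 0.104) and MALAT1 (0.58 ± 0.23; adjusted p = 0.0856) did not pass. Genes longer than 100 kb had a median of 0.15 against -0.67 pooled. For chromosome 19 the median there was -0.07 (camera adjusted p = 0.729) and for chromosome 4 -0.14 (camera adjusted p = 0.0631). The median of all genes moved by -0.10 with size factors and by 0.13 with total counts, and the share higher went from 58% to 49.7% and 68.5%.

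LMNA marks the nuclear lamina, where gene-poor chromatin lies, and was set against NLS. Long genes had a higher median, and ribosomal protein and respiratory chain mRNAs were depleted: 3833 of the 23681 genes tested passed the threshold, 1766 higher and 2067 lower. The genes that rose furthest were the long noncoding RNAs LINC00486 (2.65 ± 0.83), LINC01473 (2.05 ± 0.45), LINC02269 (1.95 ± 0.44), LINC01505 (1.95 ± 0.42), LINC01578 (1.94 ± 0.66) and LINC01876 (1.93 ± 0.44), the glypican gene GPC5 (2.09 ± 0.33), CFAP299 (1.99 ± 0.38) and CCSER1 (1.97 ± 0.42) and the deacetylase gene HDAC9 (1.95 ± 0.41), with adjusted p from 0.000102 to 0.039. RPS27 (-2.45 ± 0.54), MT2A (-2.15 ± 0.39), RPL27 (-2.09 ± 0.41), RPS18 (-2.08 ± 0.42), PRAF2 (-2.05 ± 0.39), RPL29 (-2.00 ± 0.43) and RPS15 (-1.97 ± 0.29), NOP10 (-1.95 ± 0.42) of box H/ACA particles and RPL10 (-1.86 ± 0.34) were among those that fell furthest, with adjusted p from 7.58e-05 to 0.00228. GPC5 lies on chromosome 13, 91398621 to 92867237 and RPS27 on chromosome 1, 153990762 to 153992155. Among the cytosolic ribosomal protein mRNAs, 68 of 74 fell and 0 rose (73 and 0 adjusted over the list alone). Their median was -1.37 (camera adjusted p = 5.99e-44, adjusted p = 0.331 with an estimated correlation). Of the nuclear-encoded respiratory chain mRNAs, 43 of 62 fell and 0 rose (47 and 1 adjusted over the list alone). Their median was -0.88 (camera adjusted p = 2.84e-22, adjusted p = 0.385 with an estimated correlation). On chromosome 17, 199 of 1005 fell and 3 rose (217 and 5 adjusted over the list alone). Their median was -0.33 (camera adjusted p = 1.18e-08, adjusted p = 0.436 with an estimated correlation). On chromosome 4, 138 of 752 rose and 20 fell (150 and 22 adjusted over the list alone). Their median was 0.39 (camera adjusted p = 5.05e-05, adjusted p = 0.445 with an estimated correlation). Genes longer than 100 kb had a median of 0.54 (1007 of 2572 higher, 6 lower) and genes shorter than 10 kb one of -0.65 (899 of 2046 lower, 8 higher). Within set III, the LMNA pulldown against the GFP pulldown, without inputs, had 2930 genes past the threshold, 1798 higher and 1132 lower. Of these, 561 were shared with the comparison to NLS in the same direction. There the long genes had a median of 0.01 and the ribosomal protein mRNAs one of 0.06 (camera adjusted p = 0.778). LMNA and GFP thus shared the length trend and ribosomal protein loss, and LMNA against NLS could not be tested within 1 set. LINC00486 (-0.13 ± 0.40) and RPS27 (0.07 ± 0.42) had the opposite sign and CCSER1 was 0.32 ± 0.29, none past the threshold, while GPC5 (1.01 ± 0.22) was. Chromosome trends kept their direction with medians nearer 0: up for chromosome 4 (110 rose and 16 fell, median 0.17, camera adjusted p = 0.00105, adjusted p = 0.647 with an estimated correlation), and down for chromosome 17 (104 fell and 22 rose, median -0.13, camera adjusted p = 0.000123, adjusted p = 0.616 with an estimated correlation) and chromosome 19 (101 fell and 12 rose, median -0.18, camera adjusted p = 7.87e-07, adjusted p = 0.698 with an estimated correlation). Mitochondrially encoded genes had a lower median too (8 fell and 0 rose, median -0.87, camera adjusted p = 1.53e-08, adjusted p = 0.378 with an estimated correlation). LMNA itself was 3.06 ± 0.21, and TMEFF2 (1.65 ± 0.22) and DHRS2 (1.72 ± 0.35) rose most beside it. AMBN (-2.10 ± 0.41) and FOSB (-1.78 ± 0.23) fell furthest. Counts against NLS without 1 library are given below. Size factors took the share higher from 46.1% to 60.2% and total counts to 31.6%, and it was 61.8% without the odd inputs of FBL and NPAT.

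**Figure D3:**
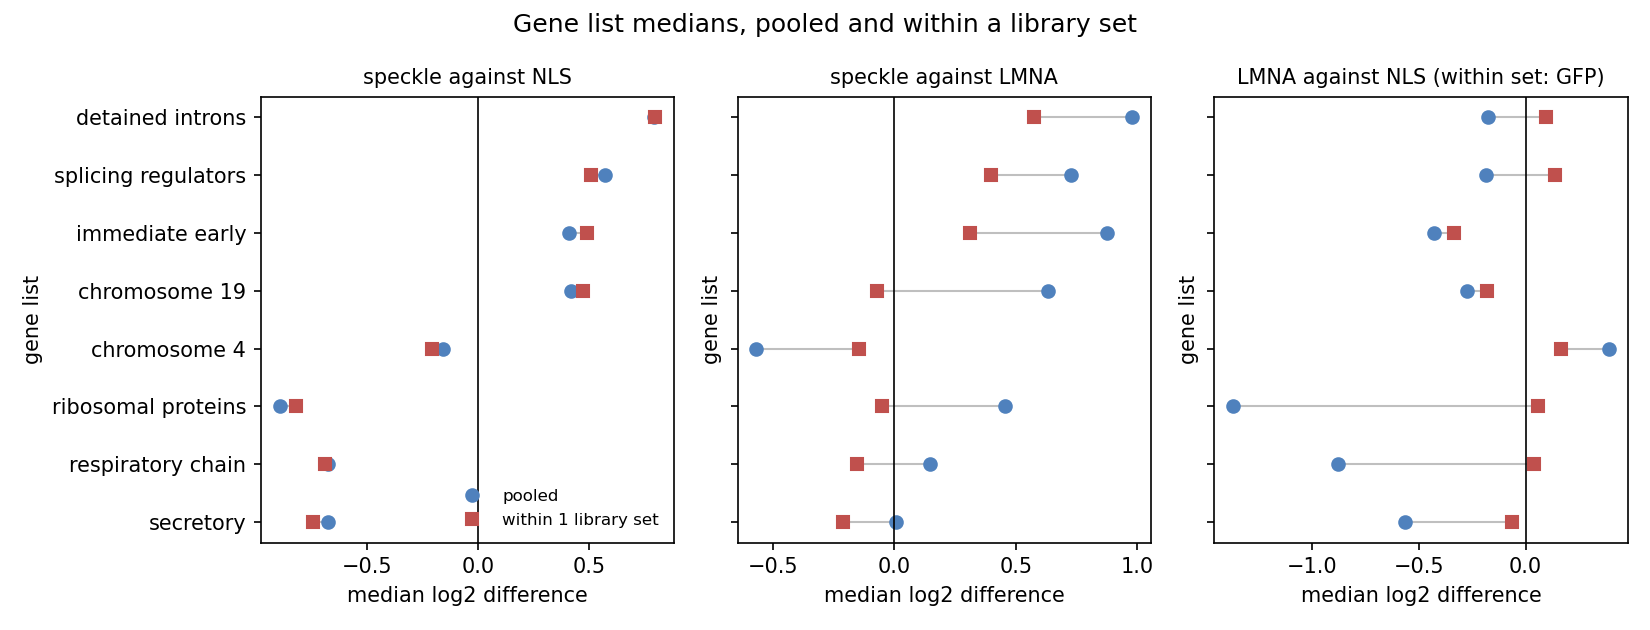
Median log2 difference of 8 gene lists, pooled and within 1 library set, for the speckle baits against NLS and LMNA and for LMNA. LMNA was set against NLS pooled and GFP within the set. Genes with detained introns had medians of 0.79 and 0.80 near speckles. Ribosomal protein mRNAs had -1.37 and 0.06 for LMNA.

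**Figure D4:**
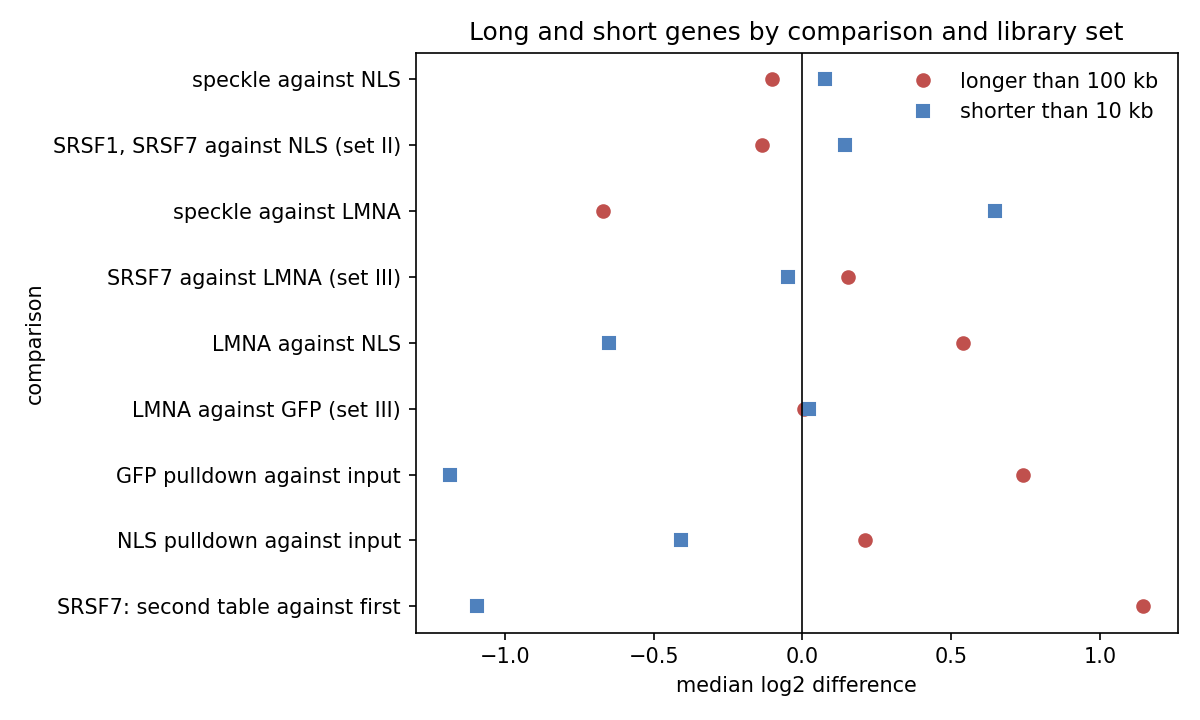
Median log2 difference of genes longer than 100 kb and shorter than 10 kb in 9 comparisons, pooled and within 1 library set. For LMNA the long genes had a median of 0.54 against NLS and 0.01 against GFP within the set.

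Fibrillarin is the methyltransferase of box C/D small nucleolar RNPs, and FBL was set against NLS to ask what lies in the nucleolus. A small nucleolar RNA host transcript and a box C/D small nucleolar RNA stood out, and few other genes passed: 163 of the 23681 genes tested passed the threshold, 104 higher and 59 lower. SNHG29, whose introns hold box C/D small nucleolar RNAs, rose by 2.19 ± 0.19 (adjusted p = 1.06e-09). Its pulldown over input was 2.17 ± 0.14 with FBL and between -0.89 (LMNA) and 0.41 (SP100) with the other 13 baits. SNORD13, the box C/D RNA U13 that guides acetylation of 18S ribosomal RNA, rose by 4.32 ± 0.39 (adjusted p = 3.81e-09), though from 1.90 ± 0.27 pulldown over input against -2.41 ± 0.28 in NLS. Within set II, from pulldowns alone, SNHG29 was 1.98 ± 0.14 and SNORD13 2.99 ± 0.28. SNHG29 lies on chromosome 17, 16438987 to 16470648 and SNORD13 on chromosome 8, 33513475 to 33513578. Other genes that rose furthest were CBX5 (1.22 ± 0.27), PRKDC (1.20 ± 0.24), MAP1B (1.13 ± 0.27), KMT2A (1.12 ± 0.25), ARHGEF18 (1.02 ± 0.24), DYNC1H1 (1.01 ± 0.19), SHISAL1 (1.01 ± 0.25) and DSP (0.99 ± 0.25) and the antisense transcript SRP14-AS1 (1.27 ± 0.24). CBX5 is a heterochromatin gene, PRKDC a DNA repair kinase and DYNC1H1 a dynein. RPL41 (-1.98 ± 0.36), LAMTOR4 (-1.96 ± 0.41), SMN2 (-1.68 ± 0.39), ROMO1 (-1.64 ± 0.41), ACOT1 (-1.59 ± 0.40), U2AF1L5 (-1.50 ± 0.33), RPSA (-1.48 ± 0.29), RPL13A (-1.34 ± 0.32), ABHD17A (-1.33 ± 0.33) and SIVA1 (-1.32 ± 0.32) fell furthest, with adjusted p from 0.0096 to 0.046. U2AF1L5 and SMN2 share reads with paralogs and are uncertain. Among the cytosolic ribosomal protein mRNAs, 3 of 74 fell and 0 rose (6 and 0 adjusted over the list alone). Their median was -0.28 (camera adjusted p = 5.13e-06, adjusted p = 0.685 with an estimated correlation). For the replication-dependent histone genes, 0 rose and 0 fell of 51 (0 and 0 adjusted over the list alone), with a median of 0.57 (camera adjusted p = 4.16e-06, adjusted p = 0.562 with an estimated correlation). From pulldowns alone within set II, 2171 genes passed (1123 higher and 1048 lower). Medians were lower for ribosomal protein mRNAs (13 fell and 0 rose, median -0.45, camera adjusted p = 1.48e-14, adjusted p = 0.647 with an estimated correlation) and splicing regulators (22 fell and 0 rose, median -0.34, camera adjusted p = 5.93e-13, adjusted p = 0.186 with an estimated correlation). The median of histone genes was higher (13 rose and 0 fell, median 0.56, camera adjusted p = 2.77e-06, adjusted p = 0.685 with an estimated correlation), and of the 5 box C/D small nucleolar RNA genes tested some rose (2 rose and 0 fell, median 1.04, camera adjusted p = 0.0438, adjusted p = 0.564 with an estimated correlation), though their median over input was -0.99 (camera adjusted p = 0.607). Without both odd inputs the medians over input were -0.14 for these, -0.57 for ribosomal protein mRNAs and 0.35 for histone genes. Gene length followed the difference to NLS (Spearman's rho 0.44, and 0.4 in pulldowns alone). Counts without 1 library are given below. The share higher went from 63.8% to 80.1% with size factors and 49.1% with total counts, and was 81.8% without both odd inputs. Replicate number as a block left 55 genes. A fit on the FBL and NLS libraries alone left 0 (edgeR; 979 at an unadjusted p under 0.05; DESeq2, on all libraries, called 784), with adjusted p = 0.524 for SNHG29 and 0.12 for SNORD13.

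SAM68 binds RNA directly, at A- and U-rich sites, and was set against NLS to ask which transcripts it approaches. ARF6 and PURA mRNAs were enriched, and NEAT1 was depleted: 4792 of the 23681 genes tested passed the threshold, 2890 higher and 1902 lower, 1762 of them at least 2-fold higher and 853 at least 2-fold lower. The small GTPase gene ARF6 (4.08 ± 0.22), the DNA- and RNA-binding gene PURA (3.84 ± 0.17) and PM20D2 (3.68 ± 0.16) were among those that rose furthest, with adjusted p from 1.87e-19 to 7.47e-17. In pulldowns alone, within set II, these were 3.93 ± 0.17, 4.00 ± 0.13 and 3.42 ± 0.12. ARF6 lies on chromosome 14, 49893082 to 49897054 and PURA on chromosome 5, 140114109 to 140125619. NPIPB5 (-2.25 ± 0.57), MIRLET7BHG (-2.03 ± 0.26), LINC01397 (-1.86 ± 0.39) and ARHGAP4 (-1.74 ± 0.34) fell furthest. NPIPB5 has many paralogs, and it did not pass in pulldowns alone (-0.66 ± 0.46; adjusted p = 0.289). NEAT1 fell by 1.53 ± 0.37. Of the mitosis and cell cycle genes, 24 of 62 rose and 0 fell (27 and 1 adjusted over the list alone). Their median was 0.41, and -0.03 under total counts (camera adjusted p = 7.01e-06, adjusted p = 0.563 with an estimated correlation). KIF14 (1.99 ± 0.20), CCND1 (1.74 ± 0.18) and KIF11 (1.27 ± 0.18) were examples. Of the DNA repair and replication genes, 22 of 85 rose and 8 fell (24 and 8 adjusted over the list alone). Their median was 0.22, and -0.22 under total counts (camera adjusted p = 0.0127, adjusted p = 0.562 with an estimated correlation). RIF1 (2.00 ± 0.19) and BRCA2 (1.97 ± 0.23) were examples. Of the nuclear pore and lamina protein mRNAs, 14 of 45 rose and 3 fell (17 and 3 adjusted over the list alone). Their median was 0.34, and -0.10 under total counts (camera adjusted p = 0.00549, adjusted p = 0.563 with an estimated correlation). SEH1L (2.09 ± 0.15) was an example. Total counts moved the median of all genes by -0.43. Part of the genes with detained introns fell: 9 of 27 fell and 0 rose (13 and 0 adjusted over the list alone). Their median was -0.37 (camera adjusted p = 0.000663, adjusted p = 0.442 with an estimated correlation). NSUN5P1 (-1.22 ± 0.20) and CCNL2 (-0.93 ± 0.16) were examples. GCLM (3.37 ± 0.18) and SLC7A11 (2.95 ± 0.30) of glutathione synthesis and cystine uptake, the p53 regulator MDM2 (1.84 ± 0.15), ZNF260 (3.37 ± 0.19) and NORAD (1.84 ± 0.18) rose. In pulldowns alone, 8562 genes passed (4358 higher and 4204 lower). Mitosis genes had 36 higher and 2 lower (median 0.44), and genes with detained introns 14 lower and 3 higher (median -0.32). The share higher went from 60.3% to 22.3% with total counts.

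PML bodies gather at sites of transcription and of interferon-induced genes, and the mean of PML and SP100 was set against NLS. Secretory mRNAs had a higher median, and the long noncoding RNA KCNQ1OT1 was lower: 901 of the 23681 genes tested passed the threshold, 299 higher and 602 lower. ZNF503 (2.03 ± 0.38), TMEM160 (1.76 ± 0.48), TMEM271 (1.51 ± 0.41) and NKX2-4 (1.47 ± 0.27) rose furthest. ZNF503 was among those that fell furthest in the NLS pulldown itself, so its rise is not specific to PML bodies. The immediate early gene EGR3 (-1.58 ± 0.32), LINC01411 (-1.44 ± 0.30) and LMCD1 (-1.33 ± 0.17) were among those that fell furthest, with adjusted p from 5.19e-05 to 0.0346. NUP98, a nuclear pore gene, rose by 0.89 ± 0.12, and KCNQ1OT1 (-1.18 ± 0.27) and NEAT1 (-1.10 ± 0.32) fell. Of the secretory and membrane protein mRNAs made at the endoplasmic reticulum, 3 of 55 rose and 1 fell (19 and 1 adjusted over the list alone). Their median was 0.44 (camera adjusted p = 1.69e-12, adjusted p = 0.523 with an estimated correlation). Of the immediate early genes, 6 of 37 fell and 1 rose (7 and 1 adjusted over the list alone). Their median was -0.09 (camera adjusted p = 0.0126, adjusted p = 0.702 with an estimated correlation). NR4A3 (-1.23 ± 0.20) and DUSP5 (-0.67 ± 0.12) were examples, but NR4A3 (1.23 ± 0.25), EGR1 (1.82 ± 0.30), FOSB (1.78 ± 0.27), JUN (1.56 ± 0.23) and FOS (1.41 ± 0.27) were higher with PML than with SP100. Of the nuclear pore and lamina protein mRNAs, 6 of 45 rose and 0 fell (12 and 0 adjusted over the list alone). Their median was 0.21 (camera adjusted p = 7.56e-07, adjusted p = 0.442 with an estimated correlation). Among 44 interferon-stimulated genes 0 rose and 4 fell (1 and 4 adjusted over the list alone), with a median of 0.14 (camera adjusted p = 0.719). Of the long noncoding RNA genes, 89 of 2139 fell and 8 rose (109 and 9 adjusted over the list alone). Their median (-0.12) and the test (camera adjusted p = 0.036, adjusted p = 0.652 with an estimated correlation) pointed down and the mean (0.39) up. The SP100 inputs were in set I. Within set II, PML against NLS had 90 genes past the threshold, 17 higher and 73 lower. All 90 were shared with the pooled comparison in the same direction. NUP98 was 1.56 ± 0.14, ZNF503 2.06 ± 0.41 and LMCD1 -1.21 ± 0.20. EGR3 (-0.74 ± 0.38; adjusted p = 0.356) did not pass. Of the secretory mRNAs 0 rose and 0 fell (median 0.42). Counts without 1 library are given below. The share higher went from 33.2% to 62.4% with size factors and 8.6% with total counts, which moved the median of all genes by -0.11. The balance reversed without the odd inputs of FBL and NPAT, which are no part of this contrast but of the fit, to 3060 higher and 1230 lower (71.3% higher).

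SMN2 assembles spliceosomal RNPs and marks gems, which lie beside Cajal bodies, and was set against NLS. Part of the cell cycle and nuclear pore mRNAs were higher: 1583 of the 23681 genes tested passed the threshold, 1045 higher and 538 lower. ZNF503 (2.43 ± 0.42) and LHFPL3 (2.23 ± 0.44) and the transcription factor genes CEBPB (1.75 ± 0.32) and FOXD3 (1.62 ± 0.34) rose furthest. U2AF1L5 (-1.88 ± 0.38), LINC01198 (-1.72 ± 0.55) and PLSCR4 (-1.40 ± 0.35) and the antisense transcript TMEM72-AS1 (-1.56 ± 0.31) fell furthest. U2AF1L5 shares its sequence with U2AF1 and is uncertain. ZNF503 was among the genes that fell furthest, and LINC01198 among those that rose furthest, in the NLS pulldown itself. Their values thus carry the shared reference and are not specific to SMN2. In pulldowns alone, within set II, ZNF503 was 2.60 ± 0.34, CEBPB 1.30 ± 0.24 and LINC01198 3.80 ± 0.27, the last with the opposite sign. Of the mitosis and cell cycle genes, 11 of 62 rose and 0 fell (18 and 0 adjusted over the list alone). Their median was 0.30 (camera adjusted p = 6.33e-07, adjusted p = 0.562 with an estimated correlation). NCAPD2 (1.02 ± 0.17) and CKAP5 (1.01 ± 0.20) were examples. Of the nuclear pore and lamina protein mRNAs, 10 of 45 rose and 1 fell (19 and 2 adjusted over the list alone). Their median was 0.35 (camera adjusted p = 1.06e-06, adjusted p = 0.442 with an estimated correlation). LMNB1 (0.95 ± 0.13) and NUP188 (1.19 ± 0.18) were examples. Of the DNA repair and replication genes, 9 of 85 rose and 0 fell (14 and 0 adjusted over the list alone). Their median was 0.16, and -0.03 under total counts (camera adjusted p = 0.000491, adjusted p = 0.442 with an estimated correlation). Of 23 spliceosomal small nuclear RNA genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone), with a median of 0.38 (camera adjusted p = 0.23). Of the long noncoding RNA genes, 88 of 2139 fell and 10 rose (70 and 9 adjusted over the list alone). Their median (-0.21) and the test (camera adjusted p = 0.00236, adjusted p = 0.562 with an estimated correlation) pointed down and the mean (0.11) up. In pulldowns alone 6669 genes passed (3054 higher and 3615 lower), and mitosis genes rose there too (34 rose and 1 fell, median 0.47, camera adjusted p = 3.97e-10, adjusted p = 0.592 with an estimated correlation). The heat shock gene HSPA1A, which has the paralog HSPA1B, was 2.96 ± 0.49 with the inputs of set I and 0.33 ± 0.33 (adjusted p = 0.497) in pulldowns alone. Counts without 1 library are given below. The share higher went from 66% to 27.6% with total counts, which moved the median of all genes by -0.19.

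WRAP53 carries telomerase and small Cajal body RNAs to Cajal bodies, and was set against NLS. Part of the histone mRNAs were higher, and NEAT1, MALAT1 and part of the genes with detained introns were lower: 1969 of the 23681 genes tested passed the threshold, 1182 higher and 787 lower. ZNF503 (2.84 ± 0.42), LHFPL3 (2.32 ± 0.42), AHR (1.98 ± 0.48) and CEBPB (1.91 ± 0.31) rose furthest, and LINC01198 (-1.83 ± 0.55), U2AF1L5 (-1.76 ± 0.34), NPIPB5 (-1.71 ± 0.54) and NEAT1 (-1.46 ± 0.36) fell furthest, with adjusted p from 0.000135 to 0.04. MALAT1 (-1.04 ± 0.33) and KCNQ1OT1 (-1.08 ± 0.31) fell as well, and TERC, the telomerase RNA, was thinly counted and did not pass (0.03 ± 0.84). Of the landmark nuclear noncoding RNAs, 3 of 7 fell and 0 rose (3 and 0 adjusted over the list alone). Their median was -0.74 (camera adjusted p = 0.0303, adjusted p = 0.528 with an estimated correlation). Of the replication-dependent histone genes, 8 of 51 rose and 0 fell (13 and 1 adjusted over the list alone). Their median was 0.72 (camera adjusted p = 1.16e-05, adjusted p = 0.563 with an estimated correlation). H4C5 (1.09 ± 0.28) and H1-3 (1.00 ± 0.27) were examples. Of the genes with known detained or retained introns, 6 of 27 fell and 0 rose (11 and 0 adjusted over the list alone). Their median was -0.45 (camera adjusted p = 4.95e-06, adjusted p = 0.368 with an estimated correlation). CLK4 (-0.84 ± 0.22) and NSUN5P1 (-0.75 ± 0.19) were examples. The fibroblast markers also passed: 1 of 8 rose and 0 fell (1 and 0 adjusted over the list alone). Their median was 1.53 (camera adjusted p = 0.0447, adjusted p = 0.508 with an estimated correlation). The gene that rose was COL6A3 (3.22 ± 0.97), at low counts. For the small nucleolar RNA host genes the median (-0.23) and the test (camera adjusted p = 0.00592, adjusted p = 0.442 with an estimated correlation) pointed down and the mean (0.06) up. In pulldowns alone, within set II, 7898 genes passed (4710 higher and 3188 lower). Histone genes had a higher median there too (18 rose and 1 fell, median 0.61, camera adjusted p = 0.00855, adjusted p = 0.857 with an estimated correlation), and genes with detained introns fell (17 fell and 0 rose, median -0.50, camera adjusted p = 6.08e-08, adjusted p = 0.186 with an estimated correlation). ZNF503 was 2.50 ± 0.34, CEBPB 1.73 ± 0.23 and NEAT1 -2.04 ± 0.27. LINC01198 had the opposite sign (3.46 ± 0.28), and NPIPB5 did not pass (-0.03 ± 0.41; adjusted p = 0.965). As for SMN2, ZNF503 and LINC01198 carry the shared reference. Counts without 1 library are given below. The share higher went from 60% to 32.7% with total counts, which moved the median of all genes by -0.14.

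NPAT drives histone gene transcription in histone locus bodies, and was set against NLS to ask whether histone mRNAs lie near it. They did not pass as a group against NLS: of 51 tested, 0 rose and 0 fell (0 and 0 adjusted over the list alone), with a median of 0.23 (camera adjusted p = 0.383), and 0.43 without both odd inputs. In all, 993 of the 23681 genes tested passed the threshold, 268 higher and 725 lower. The ephrin receptor gene EPHA6 (2.50 ± 0.72), LHFPL3 (1.70 ± 0.45), ATP2B4 (1.53 ± 0.20) and LINC01505 (1.47 ± 0.43) rose furthest, and U2AF1L5 (-2.13 ± 0.35), RPL41 (-1.75 ± 0.36), LINC00235 (-1.74 ± 0.29) and CARD9 (-1.65 ± 0.32) fell furthest, with adjusted p from 3.85e-05 to 0.0445. Of the mitochondrially encoded genes, 5 of 24 rose and 0 fell (8 and 0 adjusted over the list alone). Their median was 0.95 (camera adjusted p = 1.47e-07, adjusted p = 0.442 with an estimated correlation). MT-ATP8 was 2.40 ± 0.31. NPAT input replicate 1 was low in these transcripts (0.696% of counts against 1.599% in replicate 2). Without both odd inputs the median was 0.80, and in pulldowns alone it was 0.04 (camera adjusted p = 0.647). Of the cytosolic ribosomal protein mRNAs, 5 of 74 fell and 0 rose (6 and 0 adjusted over the list alone). Their median was -0.33 (camera adjusted p = 3.52e-07, adjusted p = 0.663 with an estimated correlation). CLK3 (-0.72 ± 0.15) and CCNL2 (-0.68 ± 0.16) of the splicing regulators fell. In pulldowns alone, within set II, 6129 genes passed (3200 higher and 2929 lower). Histone genes had a higher median there (11 rose and 2 fell, median 0.42, camera adjusted p = 0.0257, adjusted p = 0.888 with an estimated correlation) and splicing regulators fell (29 fell and 1 rose, median -0.43, camera adjusted p = 7.52e-09, adjusted p = 0.311 with an estimated correlation). ATP2B4 was 0.49 ± 0.14, CARD9 -1.94 ± 0.23 and LINC00235 -1.34 ± 0.21. EPHA6 (-0.41 ± 0.32; adjusted p = 0.363) and RPL41 (-0.52 ± 0.26; adjusted p = 0.133) did not pass. Gene length followed the difference to NLS (rho 0.495, and 0.368 in pulldowns alone). Counts without 1 library are given below. The share higher went from 27% to 48.5% with size factors and 16.8% with total counts. The balance reversed without both odd inputs, to 431 higher and 267 lower (61.7% higher). A fit on the NPAT and NLS libraries alone left 1, and the mean of all 3 references 5.

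Poly(A) selection and ribosomal depletion of SRSF7 pulldown RNA were compared in the second table to show what library preparation alone changes. Short polyadenylated mRNAs and mitochondrial mRNAs were higher after poly(A) selection, and histone mRNAs, small nuclear RNAs and MALAT1 were lower: 10091 of the 18641 genes tested passed the threshold, 5122 higher and 4969 lower. POLR3GL (3.04 ± 0.24), RPS27 (2.99 ± 0.14), RPL36AL (2.64 ± 0.13), UQCRHL (2.57 ± 0.19), RPL11 (2.53 ± 0.17), C19orf53 (2.37 ± 0.14), DBI (2.30 ± 0.13), SRP14 (2.29 ± 0.11), TCEAL9 (2.28 ± 0.15) and RPL27 (2.09 ± 0.09) rose furthest. The histone genes H4C1 (-7.30 ± 0.28), H2AC21 (-6.99 ± 0.24), H1-4 (-5.01 ± 0.48), H2BC13 (-4.99 ± 0.31), H4C3 (-4.92 ± 0.15), H4C2 (-4.85 ± 0.20), H2AC4 (-4.85 ± 0.27), H2AC12 (-4.84 ± 0.16), H4C8 (-4.68 ± 0.12) and H2AC20 (-4.62 ± 0.17) fell furthest, with adjusted p from 1.82e-21 to 0.00724. H4C1 lies on chromosome 6, 26021649 to 26022050. MALAT1, whose 3' end is a triple helix and not a poly(A) tail, fell by 2.30 ± 0.12. KCNQ1OT1 (-0.86 ± 0.10) and RMRP (-3.61 ± 0.44) fell, TUG1 rose (0.45 ± 0.09), and NEAT1 did not pass (-0.13 ± 0.09; adjusted p = 0.259). Of the replication-dependent histone genes, 36 of 40 fell and 0 rose (37 and 0 adjusted over the list alone). Their median was -3.60 (camera adjusted p = 4.51e-23, adjusted p = 0.445 with an estimated correlation). Of the spliceosomal small nuclear RNA genes, 13 of 14 fell and 1 rose (13 and 1 adjusted over the list alone). Their median was -4.73 (camera adjusted p = 6.06e-06, adjusted p = 0.445 with an estimated correlation). Of the mitochondrially encoded genes, 18 of 23 rose and 0 fell (20 and 0 adjusted over the list alone). Their median was 3.42 (camera adjusted p = 3.3e-15, adjusted p = 0.562 with an estimated correlation). Of the cytosolic ribosomal protein mRNAs, 73 of 74 rose and 0 fell (73 and 0 adjusted over the list alone). Their median was 1.17 (camera adjusted p = 1.43e-32, adjusted p = 0.562 with an estimated correlation). Genes longer than 100 kb had a median of -0.66 and genes shorter than 10 kb one of 0.68. Between the ribosome-depleted SRSF7 pulldown of the second table and the SRSF7 pulldown of the first, from different library sets, these medians were 1.15 and -1.09, and 13168 of 23815 genes passed. All 4 libraries were in set III. Total counts moved the median of all genes by 0.13 and the share higher from 50.8% to 61.6%.

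Across the 14 comparisons, 431 pairs of list and comparison were tested and 212 passed at the preset correlation, and 0 of these calls held with an estimated correlation (limma camera; 43 pairs had an unadjusted p under 0.05 there, and fry called 136). Further lists were past the threshold in these numbers of comparisons: 6 up and 2 down for genes on chromosome 13, 6 up and 3 down for genes on chromosome 18, 3 up and 3 down for telomerase and Cajal body protein mRNAs, 5 up and 3 down for ribosome biogenesis and nucleolar protein mRNAs, 0 up and 2 down for p53 target genes, 2 up and 2 down for paraspeckle protein mRNAs, 1 up and 2 down for interferon-stimulated genes, 0 up and 3 down for landmark nuclear noncoding RNAs and 5 up and 4 down for heat shock and oxidative stress genes. Under total counts the SAM68 medians of chromosomes 13 and 18 and of the heat shock genes changed sign. In the NLS pulldown, the ribosome biogenesis list and the nuclear pore list had medians of -0.14 and -0.17, which became 0.06 and 0.03 under total counts. Box C/D small nucleolar RNA genes (0.0667), blood cell markers (0.428) and neuron markers (0.413) passed in none of the comparisons, their smallest camera adjusted p being the values given, and box H/ACA small nucleolar RNAs, small Cajal body RNAs and hepatocyte markers had too few genes tested. SNORD3A, the U3 small nucleolar RNA gene, was below 10 CPM in 25 of the 56 libraries and above 100 CPM in 20. Of the 28 replicate pairs, 15 differed more than 10-fold, so its values are not reported for any comparison. It was not taken out of the fits or the gene lists.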

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

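Of the tests in this part, those on a library set, on gene length for LMNA, and on RNA from other lines or of lower quality were chosen after the result was seen; those on gene length and level near speckles and on the total count were written before. A pair of baits expected to act alike differed under a test of the difference itself. Between SRSF1 and SRSF7, both speckle proteins with all libraries in set II, pulldown over input differed for 2350 genes, 1373 higher with SRSF1 and 977 higher with SRSF7 (5599 at an unadjusted p under 0.05). MALAT1 (1.42 ± 0.33) and PURPL (2.07 ± 0.31) were higher with SRSF1, and SKI (-1.95 ± 0.22), TPGS1 (-1.98 ± 0.33) and ANKLE2 (-1.58 ± 0.15) with SRSF7; PURPL, SKI, TPGS1 and ANKLE2 were chosen after their values were seen. Between GFP and FLAG, both references, 6429 genes differed, 2892 higher with GFP and 3537 with FLAG (9370 at an unadjusted p under 0.05), with RPS27 (-2.73 ± 0.55) and RPS26 (-2.36 ± 0.27) among the lower. The GFP inputs were in set I and its pulldowns in set III, and all FLAG libraries in set II, so the construct and the library set cannot be told apart for that pair. The SRSF1 inputs stood apart from most inputs (846 and 620 genes off by 2-fold, against 54 and 43 for SRSF7), and pulldown over input carries that difference. Fewer genes passed between PML and SP100 (10 higher and 4 lower) and none between SMN2 and WRAP53 (edgeR; 776 at an unadjusted p under 0.05; no other tool was run), which does not make these pairs more alike: their profiles had r of 0.38 and 0.189, against 0.68 for SRSF1 and SRSF7.

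The enrichment near speckles of genes with detained introns held against the technical explanations that were tested, though the list call was lost with an estimated correlation (adjusted p = 0.074). If the inputs of RNPS1 from another library set had made it, few of the genes called near speckles would have stayed with SRSF1 and SRSF7 alone. Of all 4827, 94.6% stayed past the threshold in the same direction. Both comparisons share the SRSF1, SRSF7 and NLS libraries, so this speaks only to RNPS1 and is no independent repeat. The SRSF1 inputs, which stood apart from most inputs, weigh more without RNPS1. The share covers all genes called and not the detained-intron list, whose median with SRSF1 and SRSF7 alone is given above. If gene length or expression level had made it, the median of the detained-intron list would have reached 0 with both trends removed; it was 0.844 (95% bootstrap interval 0.676 to 1.00) after and 0.793 before, and 0.628 (0.512 to 0.747) for the splicing regulators. RNA of these genes may therefore lie nearer to the speckle baits than to NLS. Binding of SR proteins to the same transcripts outside speckles was not tested and stays open.

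The profile of LMNA against NLS, in which long genes had a higher median and ribosomal protein mRNAs fell, is one the library set is a candidate cause of. Of the genes past the threshold, 87.4% moved past it in the same direction between the second-table and first-table SRSF7 pulldowns, which hold no LMNA or NLS library but differ in set, and 0.7% moved in the opposite direction. If the place of LMNA had been the reason for that median, gene length would also have followed the difference between the LMNA and GFP pulldowns of set III, but Spearman's rho across genes was -0.033 there against 0.75 to NLS. What stays open is the smaller difference to GFP, such as the higher median of genes on chromosome 4.

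Input replicate 1 of FBL and of NPAT shared a shift, with 115 genes more than 2-fold up and 508 more than 2-fold down in both; 2191 and 958 genes were off by 2-fold in them, and 846 and 620 in the SRSF1 inputs, which came next. RNA of the SP100 line is argued against: SP100, near 0 in the other lines, reached at most 0.143% of its level in that line (0.249% in the highest of the other inputs). WRAP53 (74.58 and 62.68 CPM), PML (97.19 and 94.26) and LMNA (170.9 and 167.4) were high, but a 2-fold fall needs a share of 50% or more of other RNA, and these genes reached at most 21% of the level in their own lines, so those lines did not make the genes that fell; other lines stay open. A low total count is also argued against: of the 2 inputs with still lower totals, the higher had 85 genes off by 2-fold. RNA quality or the removal of ribosomal RNA in library preparation stays open. The mitochondrial ribosomal RNA MT-RNR2 was 18.3 times and 6.23 times the median of the other inputs in the FBL and NPAT libraries, but 1 input of SRSF1, without the same shift, had 64.58 CPM against 38.26 and 13.01, which keeps it from being decided. No biological explanation was tested.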

How the results depend on the processing

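The tests within 1 library set and without both odd inputs were chosen after the data were seen; the others were planned. Of 5289 repeats of 264 named gene values, 4720 kept direction and side of the threshold, 545 lost it, 9 gained it and 15 reversed. Most were picked as extremes past the threshold with replicates alike, so agreement was partly built in. Most losses came from leaving out 1 library, which leaves a group with 1 sample assumed to vary like the others. The counts of genes below moved by more than 1.5 times unless marked as within it, and counts not given stayed within it. The cause was not tested except where a setting's construction gives it. Simulations with few changed genes recovered under 20% of 2-fold changes for SAM68 (6.1%), SMN2 (4.8%), WRAP53 (9.7%), NPAT (16.7%) and FBL (19.7%). Those shares neither rank baits nor measure real power, and a missing call there shows little.

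By setting, DESeq2 gave 2205 for PML body, 2426 for SMN2, 1889 for NPAT, 784 for FBL and 2096 for NLS against GFP and FLAG. No filter beyond 1 count, which tests more genes, gave 388 for PML body, 911 for SMN2, 1087 for WRAP53, 460 for NPAT, 46 for FBL and 603 for NLS against GFP and FLAG, and a mean CPM of 5 or more, which tests fewer, gave 1410 for PML body, 1537 for NPAT and 450 for FBL. DESeq2 size factors in edgeR gave 272 for FBL, and total counts 1460 for PML body and 7392 for SAM68. The mean of all 3 references in place of NLS gave 9747 for speckle, 5442 for PML body, 5 for NPAT and 33 for FBL. Pulldowns alone, without inputs, gave 7740 for PML body, 8562 for SAM68, 6669 for SMN2, 7898 for WRAP53, 6129 for NPAT, 2171 for FBL and 10628 for LMNA; these also hold differences between the lines. A fit on the libraries of the contrast alone gave 11231 for NLS pulldown, 8258 for GFP pulldown, 8948 for FLAG pulldown, 9169 for speckle, 6664 for PML body, 10004 for SAM68, 3965 for SMN2, 7201 for WRAP53, 1 for NPAT, 0 for FBL, 6132 for LMNA and 2221 for NLS against GFP and FLAG. Without both odd inputs the counts were 5836 for FLAG pulldown, 7316 for speckle, 4290 for PML body, 3642 for SMN2, 4249 for WRAP53, 6392 for LMNA and 3559 for NLS against GFP and FLAG, and within that range 698 for NPAT (364 shared) and 242 for FBL (100 shared). Within 1 library set they were 90 for PML body, 3417 for speckle against LMNA and 729 for NLS against GFP and FLAG, and within that range 6009 for speckle and 2930 for LMNA. TMM without mitochondrial and small RNA genes moved no count beyond 1.5 times.

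Leaving out each library in turn gave 2840 to 3968 for NLS pulldown, 8998 to 12064 for GFP pulldown, 769 to 1543 for FLAG pulldown, 2879 to 4949 for speckle, 69 to 762 for PML body, 3531 to 4067 for SAM68, 603 to 1480 for SMN2, 680 to 1249 for WRAP53, 115 to 5342 for NPAT, 8 to 6309 for FBL, 1802 to 4521 for LMNA, 6608 to 8632 for speckle against LMNA, 268 to 1846 for NLS against GFP and FLAG and 7746 to 10053 for poly(A).

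Replicate numbers paired the fractions weakly at most: across genes, the difference between replicates in the pulldown and in the input had r between -0.21 and 0.37, over 0.1 for 7 of 14 baits. Bait and replicate number as a block gave 55 for FBL. Of the 431 list tests, 212 passed, 0 with an estimated correlation, 136 with fry, 206 with size factors and 208 with the block. Profiles best matched by their own replicate were 13, 20 at a mean CPM of 5 or more, and 23 with the shared input mean. The bait gene check gave 10 of 11 under both scalings.

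Where the main or the repeated value passed the threshold, named genes changed direction only within 1 library set and in pulldowns alone. Within the set, LINC00486 (-0.13), RPS15 (0.089) and RPS27 (0.074) did so for LMNA against GFP, none past the threshold. For speckle against LMNA, ADGRL3 (0.31), FGF13 (0.52), GPM6A (0.28) and SAMD5 (0.06) did so, and CHSY3 (1.65), GALNT13 (1.28) and PPFIA2 (0.92) also passed. In pulldowns alone, KCNQ1OT1 (-0.62) and NEAT1 (-1.51) did so for speckle, LINC01198 for SMN2 (3.80) and for WRAP53 (3.46), and EPHA6 for NPAT (-0.41).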

Other observations

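DNA repair genes POLE (1.34 ± 0.12) and FANCG (1.36 ± 0.14) were higher near speckles than with NLS, as were the ribosome assembly gene NOP56 (1.19 ± 0.18), which hosts small nucleolar RNAs, and the host transcript SNHG15 (0.93 ± 0.13). With SRSF1 and SRSF7 alone, within set II, these were 1.26 ± 0.12, 1.36 ± 0.14, 1.20 ± 0.19 and 0.98 ± 0.14. SAM68 had 2.19 ± 0.20 for EIF2AK2, the kinase that senses double-stranded RNA, 3.02 ± 0.31 for the ribosome assembly gene KRR1, 2.30 ± 0.29 for the p53 target RRM2B and 1.00 ± 0.13 for BRCA1.

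U2AF1 and its copy U2AF1L5, whose reads cannot be told apart by symbol, were lower with SMN2 (-1.62 ± 0.38 and -1.88 ± 0.38) and WRAP53 (-1.98 ± 0.37 and -1.76 ± 0.34) than with NLS. NORAD was higher with SAM68 (1.84 ± 0.18), SMN2 (1.35 ± 0.18), WRAP53 (1.37 ± 0.18) and FBL (0.81 ± 0.18). These values all rest on the same 2 NLS pulldowns and inputs.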
